A study of Mus musculus with 9 samples.

How the data were processed

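RNA sequencing was carried out on corona radiata cells, the granulosa-derived cumulus cells that surround the oocyte, from adult mice after hormonal stimulation with PMSG and hCG. PMSG drives follicle growth and hCG triggers ovulation. The labels add the term "J4" to this treatment without explaining it. They give 3 genotypes with 3 libraries each, 9 libraries in all. The genotypes are wild type (WT), a double knockout of the liver X receptors (LXR DKO), and LXR DKO mice that carry a transgene named TG-AMH-LXRb, called transgenic here. The labels do not describe the promoter or the coding sequence of the transgene, or the deleted part of either receptor gene. They say that libraries were made in triplicate. They do not say that a replicate number marks a shared animal, litter or day, and give no sequencing or library batch. Nothing says that the libraries came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Total RNA was isolated with a column kit and sequenced on an Illumina NextSeq, per the labels' protocols.

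The authors deposited 1 matrix of RPKM values (reads per kilobase of gene, scaled to the size of the library) for 54838 mouse genes listed by Ensembl identifier, with 1 column per library. Each column was assigned to a sample by its name. The column names of the transgenic libraries differ from the sample descriptions in 1 letter, and were matched through the letters TG and the replicate number. The number of columns of values not used was 0. The submitters' processing notes name cutadapt, HISAT2 2.1.0, HTSeq 0.5.4p5, DESeq2 1.2.8 and the mm10 build, without saying what each did. The annotation release, the strand setting, the handling of reads that map to several places and the reads that set the library size are not given in the sources used here. Genes with near-identical copies, and genes that overlap on opposite strands, therefore have uncertain values, because reads of 1 can be counted in the other or lost from both.

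The deposited RPKM values carry no read counts, but read numbers could be worked back. Within a library the values of a gene are whole multiples of the value of 1 read, which depends on the gene's length. With the summed exon length of each gene in GENCODE M21, all 9 values were whole reads, to within 0.02 reads, for 37146 of the 37863 genes with a value above 0 in any library (98.1%). Another 602 genes gave whole reads only with another length, and 115 gave none. The genes that did not match lay mostly on chromosomes 18 and 19, where 73.9% and 56.2% of genes matched. In every library at least 97.8% of the values above 0 were whole reads. Mitochondrial genes are all listed at 0. The library scale of the RPKM values differed by up to 4.26% from the total of reads in genes, and by up to 1.57% from a median-of-ratios size factor. Reads in genes ranged from 31748441 to 46922411 per library. A gene with 1 kb of exons needs an RPKM of 0.0638 to 0.0965, depending on the library, for 3 reads. No 2 libraries of a group held the same values: the lowest chi-square per degree of freedom between them was 16.8. Symbols came from the deposited matrix, and gene types and the mm10 coordinates printed here from GENCODE M21. For 1233 genes the matrix gave no symbol and the identifier was used.

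The test was chosen before the data were examined. It was to be a quasi-likelihood test on counts if counts were present and limma on log values if only RPKM values were, and the second was used. Values were transformed to log2(RPKM + 1), with a pseudocount of 1. Genes with an RPKM of at least 1 in at least 3 of the 9 libraries were kept, which left 16422 genes. All 9 libraries entered 1 linear model in limma 3.58.1 (R 4.3.3), with genotype as the only factor, moderated variances and a mean-variance trend. Each gene thus has 1 spread for all genotypes. The chi-square per degree of freedom between libraries was 46.0 to 139 within WT, but 16.8 to 20.9 within transgenic. The p-values of comparisons with WT may therefore be too small, and those of transgenic minus LXR DKO too large. Comparisons were LXR DKO minus WT, transgenic minus LXR DKO and transgenic minus WT. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and log2 fold changes are given with their standard error (SE). Because of the pseudocount a log2 fold change understates the change of genes with low values.

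Gene lists fixed before the data were examined comprised 23 pathway lists and 10 cell type lists. Each was tested with camera in limma, with a preset correlation between genes of 0.01, and adjusted by Benjamini-Hochberg over the 32 lists that had at least 5 tested members. The endothelial list had fewer and was not tested. Each list has its count of genes past the threshold over all genes, and a count adjusted over the list alone. Camera and fry, an alternative list test, look for a shift of a list in 1 direction. The mixed test of fry counts changes either way. A cell type score is the mean log2(RPKM + 1) of all listed markers in a library. Genes to be named were taken from a set fixed by a rule, of which the text names a part: Nr1h3, Nr1h2 and Amh in every library; the 8 largest rises and the 8 largest falls per comparison among genes past the threshold, with groups that do not overlap, a mean RPKM of at least 1 in the higher group and a symbol other than a predicted or clone name; up to 4 members of each list with the smallest adjusted p; and any LXR target on the list. Genes reversed by the transgene were those past the threshold in both LXR DKO minus WT and transgenic minus LXR DKO with opposite signs. Because comparisons share libraries, overlaps and correlations were set beside 100 simulated data sets with no genotype effect and beside the overlap of independent lists. The position of transgenic libraries between LXR DKO and WT was set beside 100 simulated data sets in which LXR DKO and transgenic libraries have the same mean, a test chosen after the values were seen.

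The gene test was tested on simulated data with 50 changed genes per fold size, drawn from the means and spreads of these libraries. Each simulated gene had the same spread in all genotypes, unlike the data. For LXR DKO minus WT it recovered 18% of 1.5-fold changes, 72% of 2-fold, 100% of 4-fold and 100% of 8-fold changes (16205 genes, 8 false calls). For transgenic minus LXR DKO it recovered 18%, 70%, 90% and 100% (16185 genes, 9 false calls). For transgenic minus WT it recovered 14%, 66%, 98% and 98% (16199 genes, 3 false calls). Other settings tried were limma without the trend, quantile normalization, no filter, a filter of RPKM of at least 5 in 3 libraries, a pseudocount of 0.1, only the 2 genotypes compared, the replicate number as a block, each library left out in turn, and for lists an estimated correlation and fry. Settings chosen after seeing the data were voom in limma on the reads worked back, leaving out the 2 libraries with the most oocyte RNA, and a score of oviduct markers as a covariate. That score goes partly with genotype (1.47 to 3.84 in WT, 2.40 to 3.21 in LXR DKO and 3.59 to 4.15 in transgenic libraries). The covariate therefore also takes up genotype differences, and a call lost with it does not show that oviduct RNA was the cause.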

Results

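Gene expression was measured by RNA sequencing in mouse corona radiata cells, the granulosa-derived cells that surround the oocyte, after ovarian stimulation with PMSG and hCG. The 9 libraries fell into 3 genotypes of 3 libraries each: wild type (WT), a double knockout of both liver X receptors (LXR DKO), and LXR DKO with the transgene TG-AMH-LXRb (transgenic). Liver X receptors are nuclear receptors that bind oxysterols and regulate genes of cholesterol and lipid handling. The deposited values are RPKM. Reads in genes, worked back from those values, numbered 45346007, 37877381 and 45525133 in WT 1 to 3, 43379910, 33043432 and 34963059 in LXR DKO 1 to 3, and 46922411, 31748441 and 33698387 in transgenic 1 to 3. Means are given as RPKM ± SD with n = 3 libraries, and fold changes as log2 fold change ± SE on the log2(RPKM + 1) scale, from limma with Benjamini-Hochberg adjustment over 16422 genes.

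The targeted genes were examined in every library. Nr1h2, which encodes LXR beta (ENSMUSG00000060601, mm10 chromosome 7, 44549616 to 44553951, minus strand), measured 45.7, 39.7 and 39.7 RPKM in WT 1 to 3. It measured 3.57, 2.85 and 3.03 RPKM in LXR DKO 1 to 3 and 4.83, 5.28 and 6.70 RPKM in transgenic 1 to 3. Nr1h2 fell in LXR DKO by 3.36 ± 0.12 (limma, adjusted p = 6.74e-06) and remained lower than in WT in the transgenic libraries (-2.70 ± 0.12, adjusted p = 1.6e-05). The mean of 5.6 ± 0.974 RPKM in the transgenic libraries against 3.15 ± 0.373 in LXR DKO (SD, n = 3) was a difference of 0.66 ± 0.12 that did not pass the threshold (adjusted p = 0.129), although every transgenic library lay above every LXR DKO library. Nr1h3, which encodes LXR alpha (ENSMUSG00000002108, chromosome 2, 91184061 to 91202834, minus strand), measured 3.50, 5.72 and 4.95 RPKM in WT, 1.08, 0.713 and 0.933 RPKM in LXR DKO, and 0.395, 0.819 and 0.539 RPKM in the transgenic libraries. It fell in LXR DKO by 1.57 ± 0.18 (adjusted p = 0.00148) and showed no change past the threshold between transgenic and LXR DKO (-0.27 ± 0.18, adjusted p = 0.751). The labels do not give the deleted parts or the transgene sequence, so the reads left on both genes check the knockouts only in part, and transcripts of the transgene are counted only where they carry annotated exons of the mouse gene. Amh (ENSMUSG00000035262, chromosome 10, 80805243 to 80807648), a granulosa hormone gene whose symbol stands in the transgene's name, was low in every library. It measured 0.245, 0.307 and 0.255 RPKM in WT, 0.800, 0.304 and 0.382 RPKM in LXR DKO and 0.207, 0.135 and 0.406 RPKM in transgenic libraries, and was below the filter for testing.

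**Figure D1:**
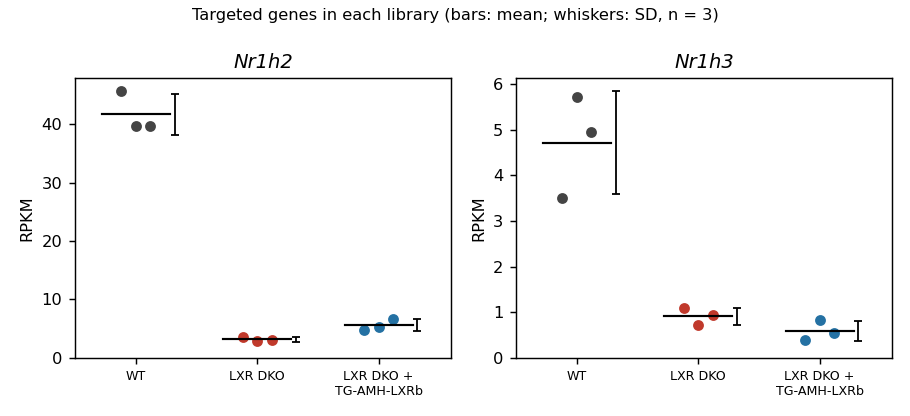
RPKM of Nr1h2 and Nr1h3 in each library (points), with the mean (bar) and SD (whisker) of the 3 libraries per genotype. Nr1h2 lies between 39.7 and 45.7 RPKM in WT, between 2.85 and 3.57 in LXR DKO and between 4.83 and 6.70 in the transgenic libraries.

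Markers of other cell types varied between libraries. The oocyte score, a mean log2(RPKM + 1) over 20 markers, was 5.09 in WT 1 and 3.31 in LXR DKO 1 and at most 1.51 in the other libraries. The oocyte growth factor gene Gdf9 measured 126 RPKM in WT 1 and 136 in LXR DKO 1. The oocyte marker H1foo measured 256 and 235 RPKM there, 6.05 in LXR DKO 2 and 6.43, 26.1 and 13.6 in transgenic 1 to 3. In WT 2, WT 3 and LXR DKO 3 it measured 0.0675, 0.354 and 0.700 RPKM. Leaving out WT 1 and LXR DKO 1, called oocyte-containing here, thus did not remove all oocyte RNA. The erythroid score was 7.31 in WT 3, where the globin gene Hbb-bs measured 2663 RPKM against at most 319.5 in any other library. The oviduct epithelium score was 1.48, 1.47 and 3.84 in WT, 2.40, 3.21 and 2.90 in LXR DKO and 3.94, 3.59 and 4.15 in the transgenic libraries. Ovgp1, the oviduct glycoprotein gene, measured 52.2, 109 and 1125 RPKM in WT, 226, 655 and 477 in LXR DKO and 1266, 1857 and 1679 in transgenic libraries. The macrophage score was 3.74, 3.94 and 4.51 in WT, 3.92, 4.43 and 4.47 in LXR DKO and 3.26, 3.06 and 3.50 in transgenic libraries. On the first principal component, which held 42.5% of the variance, WT 3 (16.2) lay apart from WT 1 (-52.4) and WT 2 (-38.8).

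**Figure D2:**
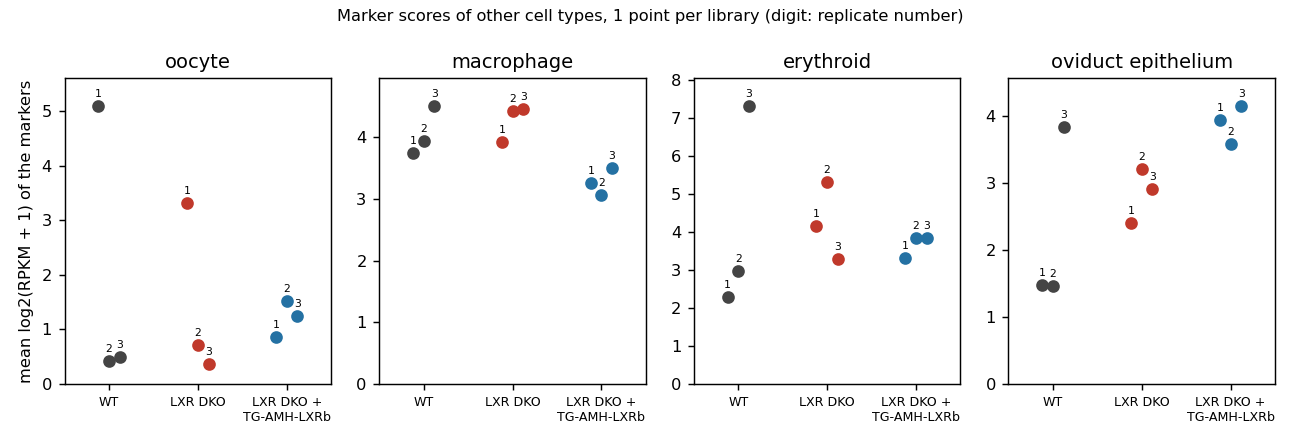
Scores of oocyte, macrophage, erythroid and oviduct epithelium markers (mean log2(RPKM + 1) of each list) by genotype, with 1 point per library and its replicate number. The oocyte score is highest in WT 1 (5.09) and LXR DKO 1 (3.31), the erythroid score in WT 3 (7.31), and all 3 transgenic libraries lie below every other library for macrophage markers.

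LXR DKO and WT libraries were compared to see which genes differ between these genotypes in the collected corona radiata samples, which also held RNA of other cells. Among listed genes that fell were the matrix-linking gene Tnfaip6, from 388 ± 63.2 to 103 ± 12.4 RPKM, the estradiol-forming enzyme gene Hsd17b1, from 84.7 ± 5.88 to 34.5 ± 12 RPKM, and the immediate early transcription factor gene Jun, from 92.0 ± 7.29 to 52.1 ± 3.66 RPKM (SD, n = 3). The prostaglandin F receptor gene Ptgfr rose from 2.69 ± 0.733 to 9.58 ± 1.39 RPKM and the versican-cleaving protease gene Adamts1 from 13.2 ± 1.91 to 39.6 ± 9.57 RPKM. Of known LXR targets, Mylip and Lpl fell and Abca1 did not pass the threshold. Of the fixed lists, glycolysis and inflammatory genes were higher, and granulosa identity, immediate early and dissociation stress, and oxidative phosphorylation genes were lower in camera with a preset correlation. None of the 5 calls held with an estimated correlation (adjusted p = 0.902 for the first 4 and 0.995 for oxidative phosphorylation).

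Of 19 LXR targets tested, 4 fell, 1 rose and 14 did not pass the threshold in LXR DKO. Adjusted over the list alone, 7 fell and 6 rose, and the list as a whole did not pass in 1 direction (camera adjusted p = 0.806, median log2 fold change -0.17). Members that move both ways can cancel in that test. The mixed test of fry, which counts changes either way, passed (adjusted p = 1.41e-06). It passed for other lists too, such as luteinization (2.9e-06) and extracellular matrix (5.19e-06), so it does not single out LXR targets. Mylip, an E3 ligase gene that lowers the LDL receptor, fell by 1.06 ± 0.19 (4.36 ± 1.14 to 1.55 ± 0.269 RPKM, limma adjusted p = 0.0106). The lipoprotein lipase gene Lpl fell by 0.78 ± 0.15 (17.5 ± 3.73 to 9.61 ± 1.21 RPKM, adjusted p = 0.0162), and the desaturase gene Scd2 by 0.86 ± 0.17 (378 ± 83.7 to 206 ± 32.2 RPKM, adjusted p = 0.018). The calls of Lpl and Scd2 were each lost without WT 1, WT 2 or LXR DKO 2, with log2 fold changes over all omissions of -0.96 to -0.67 and -1.04 to -0.72 (adjusted p up to 0.0591 and 0.0647). Both were also lost with only the 2 genotypes compared (adjusted p = 0.051 and 0.0571) and without both oocyte-containing libraries, WT 1 and LXR DKO 1, a setting chosen after seeing the data (0.088 and 0.0907), and that of Scd2 with no filter (0.0569). The E3 ligase gene Rnf145 fell by 0.46 ± 0.11 (adjusted p = 0.0333), and the phospholipid acyltransferase gene Lpcat3 was the 1 target that rose (81.9 ± 13.8 to 118 ± 10 RPKM, 0.54 ± 0.13, adjusted p = 0.0308). The call of Rnf145 held only without WT 3 or LXR DKO 1 (adjusted p up to 0.11), and that of Lpcat3 was lost without LXR DKO 2, LXR DKO 3 or any transgenic library (up to 0.117). Both were lost with no filter (0.0728 and 0.0757) and with only the 2 genotypes compared (0.0895 and 0.0868), and that of Rnf145 with quantile normalization (0.056) and without the oocyte-containing libraries (0.0713). The cholesterol exporter gene Abca1 measured 13.8 ± 4.46 and 17.7 ± 2.96 RPKM (0.37 ± 0.23, adjusted p = 0.355), and Abcg1 3.45 ± 1.07 and 2.84 ± 1.94 RPKM (-0.30 ± 0.32, adjusted p = 0.608). Apoe, the apolipoprotein E gene, measured 315 ± 95.2 and 193 ± 23.1 RPKM (-0.67 ± 0.19, adjusted p = 0.0583). The log2 fold changes of the remaining targets, none past the threshold, were 1.62 for Tgm2, 0.77 for Scd1, 0.61 for Fasn, 0.45 for Smpdl3a, 0.45 for Abca7, 0.39 for Mertk, 0.011 for Tmem97, -0.17 for Pltp, -0.21 for Arl4c, -0.36 for Srebf1 and -0.90 for Apoc1. Among 24 cholesterol synthesis genes, 2 rose and 22 did not pass, with the same 2 adjusted over the list alone (camera adjusted p = 0.264). These were Sc5d (8.66 ± 1.13 to 15 ± 2.28 RPKM, 0.73 ± 0.14, adjusted p = 0.016) and Dhcr7 (0.60 ± 0.12, adjusted p = 0.018), which encode late enzymes of the pathway. Both calls were lost without LXR DKO 3, and that of Dhcr7 also without LXR DKO 2 (adjusted p up to 0.0636 and 0.0741). The former was also lost without the oocyte-containing libraries (0.0509) and the latter with only the 2 genotypes compared (0.0507). None of 20 sterol uptake and lipid droplet genes passed the threshold over all genes or over the list alone (camera adjusted p = 0.656).

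Granulosa identity genes were lower in LXR DKO. Of 21 tested, 8 fell, 0 rose and 13 did not pass, with 12 lower when adjusted over the list alone (median log2 fold change -0.45, camera adjusted p = 0.00103; adjusted p = 0.902 with an estimated correlation and 0.0587 with fry). In the same libraries all 11 oviduct epithelium genes had positive log2 fold changes, 0 past the threshold (median 0.56, camera adjusted p = 0.308), with scores of 2.40, 3.21 and 2.90 in LXR DKO 1 to 3 and 1.48, 1.47 and 3.84 in WT 1 to 3. Hsd17b1 fell by 1.32 ± 0.22 (limma adjusted p = 0.009). Irx3, a homeobox gene of granulosa cells, fell by 0.96 ± 0.21 (adjusted p = 0.0215), a call lost without WT 1, WT 2, LXR DKO 2 or LXR DKO 3 (-1.20 to -0.80, adjusted p up to 0.0897), with no filter (0.0607) or with only the 2 genotypes compared (0.0542). Of 22 cumulus expansion and ovulation genes, 3 fell, 1 rose and 18 did not pass, with 7 lower and 3 higher over the list alone (camera adjusted p = 0.799). Tnfaip6 fell by 1.89 ± 0.17 (adjusted p = 0.000396) and Adamts1 rose (adjusted p = 0.00152). Of 18 luteinization genes, 2 rose and 2 fell, with 3 each way over the list alone. The list's mean log2 fold change was 0.02 and its median -0.05, and the test did not pass (camera adjusted p = 0.988). Ptgfr rose by 1.53 ± 0.16 (adjusted p = 0.00098). Cited1, a transcriptional coregulator gene, fell by 0.81 ± 0.14 from 2.67 ± 0.115 to 1.09 ± 0.208 RPKM (adjusted p = 0.0108; 0.0505 without LXR DKO 3). Of 15 steroidogenesis genes, 2 fell, 1 rose and 12 did not pass, with 4 lower and 1 higher over the list alone (camera adjusted p = 0.799, direction lower, with a mean of -0.16 and a median of 0.00). Star, the carrier that brings cholesterol into mitochondria, fell by 0.83 ± 0.20 (118 ± 13.9 to 67.0 ± 15.2 RPKM, adjusted p = 0.0333). Akr1c18, an enzyme gene of progesterone inactivation, rose by 0.71 ± 0.15 from 2459 ± 348 to 3988 ± 245 RPKM (adjusted p = 0.0223). The call of Star was lost without WT 1, WT 2, any LXR DKO library or transgenic 1 (-0.94 to -0.63, adjusted p up to 0.0962), and that of Akr1c18 without WT 1, LXR DKO 2 or LXR DKO 3 (0.59 to 0.80, adjusted p up to 0.0778). Both were also lost with no filter (adjusted p = 0.0883 for Star and 0.477 for Akr1c18), with only the 2 genotypes compared (0.0538 and 0.0718) and without the oocyte-containing libraries (0.0942 and 0.0701), and that of Star with quantile normalization (0.0587).

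Immediate early and dissociation stress genes, 1 list fixed to cover also the stress of dissociating cells, were lower in LXR DKO. Of 21 tested, 7 fell, 0 rose and 14 did not pass, with 10 lower and 1 higher over the list alone (median -0.33, camera adjusted p = 0.00105; adjusted p = 0.902 with an estimated correlation). The AP-1 genes Jun and Fos fell by 0.81 ± 0.10 and 0.71 ± 0.12 (limma adjusted p = 0.00201 and 0.00774), the zinc finger gene Egr2 by 1.11 ± 0.18 (119 ± 13 to 55.1 ± 10.3 RPKM, adjusted p = 0.0075) and the orphan nuclear receptor gene Nr4a2 by 0.89 ± 0.15 (adjusted p = 0.00959). The call of Egr2 was lost with both oocyte-containing libraries left out (-0.95, adjusted p = 0.0556). Glycolysis genes were higher: 3 of 18 rose, 0 fell and 15 did not pass, with 8 higher over the list alone (median 0.29, camera adjusted p = 0.000474; adjusted p = 0.902 with an estimated correlation). The phosphofructokinase gene Pfkp rose by 0.48 ± 0.09 (14.4 ± 1.2 to 20.4 ± 1.17 RPKM, adjusted p = 0.013; 0.0594 without LXR DKO 3 and 0.0509 without the oocyte-containing libraries). Of 24 nuclear oxidative phosphorylation genes, 6 fell, 1 rose and 17 did not pass, with 9 lower and 2 higher over the list alone (median -0.15, camera adjusted p = 0.0485). With an estimated correlation the adjusted p = 0.995, and the list's call was lost without WT 3, LXR DKO 2, LXR DKO 3 or transgenic 3 (adjusted p = 0.24, 0.0678, 0.117 and 0.0572), with a median of -0.081 without WT 3. It was also lost with quantile normalization (median -0.067, adjusted p = 0.289), fry (0.202), the stricter filter (0.0826), a pseudocount of 0.1 (0.0503), only the 2 genotypes compared (0.0556) and voom (0.052). Cox6c, a subunit gene of cytochrome c oxidase, fell by 0.61 ± 0.09 (20.9 ± 2.25 to 13.3 ± 0.216 RPKM, adjusted p = 0.00553). Inflammatory and NF-kB genes were higher, with 15 of 16 above 0 but only 1 past the threshold and 3 over the list alone (median 0.54, camera adjusted p = 0.00103). With an estimated correlation the adjusted p = 0.902, and with the preset correlation it was 0.0678 without LXR DKO 2, where the median was 0.30, and 0.0684 with the stricter filter. With fry it was 0.202. The cytokine gene Il1b rose by 1.73 ± 0.35 from 1.68 ± 0.385 to 8.49 ± 4.30 RPKM (adjusted p = 0.0175), a call lost without WT 1, LXR DKO 2 or LXR DKO 3 (adjusted p up to 0.0717) or with no filter (0.0541). Beside these lists, the macrophage score was 3.92 to 4.47 in LXR DKO and 3.74 to 4.51 in WT, and none of 15 macrophage genes passed the threshold. The neutrophil score lay between 1.68 and 2.69 in the LXR DKO libraries and between 1.12 and 1.76 in the WT libraries. Of 6 neutrophil genes 5 had positive log2 fold changes and 0 passed (median 0.97, camera p = 0.022, adjusted p = 0.117; adjusted p = 0.902 with an estimated correlation), and the score was highest in LXR DKO 2, without which the inflammatory list did not pass.

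The largest rises in LXR DKO were in Ifi202b, Hal, Rbm45 and Acvrl1. Ifi202b, an interferon-inducible gene (ENSMUSG00000026535, chromosome 1, 173962568 to 173982744), rose by 4.30 ± 0.19, from 0.770 ± 0.216 to 33.8 ± 2.27 RPKM (adjusted p = 1.14e-05). The family has close copies, so its reads are uncertain. The histidine ammonia-lyase gene Hal (ENSMUSG00000020017, chromosome 10, 93488768 to 93519304) rose by 3.88 ± 0.15, from 0.259 ± 0.108 to 17.7 ± 3.72 RPKM (adjusted p = 6.74e-06). The RNA-binding protein gene Rbm45 rose from 2.37 ± 0.588 to 29.7 ± 0.342 RPKM and Acvrl1, a type I receptor gene of the TGF-beta family, from 2.01 ± 0.406 to 20.3 ± 2.75 RPKM. Fcrlb (2.82), Paip1 (2.73), A2m (2.52) and Fgd5 (2.49) had the next largest log2 fold changes. After Nr1h2, the largest fall was in Cntnap5a (chromosome 1, 115684756 to 116587323), from 8.95 ± 3.01 to 0.0286 ± 0.0170 RPKM (-3.23 ± 0.21, adjusted p = 9.69e-05). Cercam fell by 2.48 ± 0.14 (52.1 ± 9.51 to 8.45 ± 0.975 RPKM, adjusted p = 3.8e-05), the leukocyte surface glycoprotein gene Cd52 by 2.09 ± 0.22 (133 ± 21.8 to 30.5 ± 5.71 RPKM, adjusted p = 0.0012), and the chromatin remodelling gene Smarcd1 by 2.04 ± 0.15 (7.19 ± 0.826 to 1.00 ± 0.356 RPKM, adjusted p = 0.000143). Abhd14b, Enc1 and Lrrn3 fell by 2.08, 1.98 and 1.93. All 16 calls held in each omission testing the gene, which cannot exclude DNA that differs between lines.

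**Figure D3:**
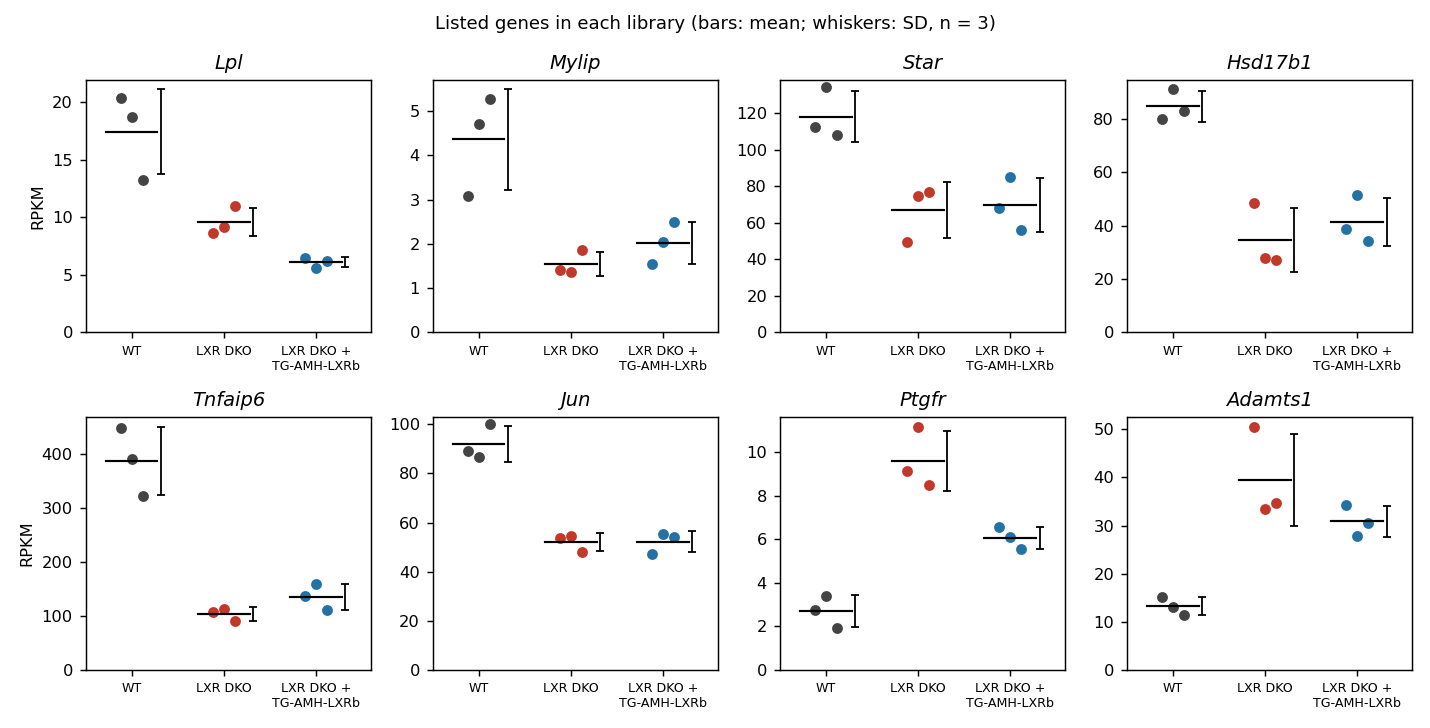
RPKM of 8 listed genes in each library (points) by genotype, with the mean (bar) and SD (whisker) of 3 libraries. Lpl, Mylip, Star, Hsd17b1, Tnfaip6 and Jun are lower in LXR DKO than in WT and Ptgfr and Adamts1 higher; none of the 8 differs past the threshold between LXR DKO and the transgenic libraries.

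In all, 1739 genes differed between LXR DKO and WT in limma, 570 higher and 1169 lower, of which 276 were at least 2-fold apart (101 higher, 175 lower). The values of the groups did not overlap for 28.9% of the genes tested, against 10% by chance. The count depended on single libraries: it was 947 without WT 1, 991 without WT 2, 839 without LXR DKO 2, 606 without LXR DKO 3 and 1101 without both oocyte-containing libraries. It was 1032 with no filter, 902 with only the 2 genotypes in the fit and 2721 with the oviduct score as a covariate.

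Transgenic and LXR DKO libraries were compared to see which genes differ between the knockout with and without the transgene. Cav1 and Cav2, neighbouring genes of the coat proteins of caveolae, were nearly lost in the transgenic libraries. Gpx3, the secreted glutathione peroxidase gene, rose from 69.2 ± 12 to 215 ± 12.8 RPKM (SD, n = 3), and A2m, a protease inhibitor gene raised in LXR DKO, fell back from 19.5 ± 4.55 to 3.94 ± 0.142 RPKM. Macrophage markers were lower and oviduct markers higher as lists in camera with a preset correlation, although no single oviduct gene passed. Neither list passed with an estimated correlation (adjusted p = 0.412 and 0.586). None of the tested LXR targets, granulosa identity, ovulation, steroidogenesis or luteinization genes passed the threshold.

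Cav1 (ENSMUSG00000007655, chromosome 6, 17306335 to 17341452) measured 249.5 ± 20.4 RPKM in LXR DKO and 0.739, 0.934 and 7.97 RPKM in transgenic 1 to 3, and fell by 6.33 ± 0.53 (limma adjusted p = 0.00394). Cav2 (ENSMUSG00000000058, chromosome 6, 17281185 to 17289115) fell by 3.66 ± 0.19, from 19.6 ± 5.80 to 0.590 ± 0.142 RPKM (adjusted p = 0.000337). In WT they measured 239 ± 31.4 and 23.4 ± 3.72 RPKM. Gpx3 (ENSMUSG00000018339, chromosome 11, 54902453 to 54910377) rose by 1.64 ± 0.14 (adjusted p = 0.00416). The ribosomal protein gene Rps2 (ENSMUSG00000044533), whose many copies make its reads uncertain, rose by 0.79 ± 0.07 (21.2 ± 0.910 to 37.4 ± 1.05 RPKM, adjusted p = 0.00394). Zfp125 (ENSMUSG00000069755), annotated as a transcribed pseudogene, fell by 2.19 ± 0.15 (5.41 ± 0.547 to 0.413 ± 0.200 RPKM, adjusted p = 0.00133). These 5 calls held without each library in turn wherever the gene was still tested. That of A2m (-2.03 ± 0.18, adjusted p = 0.00416) was lost only without LXR DKO 3 (adjusted p = 0.0508). The other named calls were lost without several libraries each. The tRNA modification gene Thg1l (1.06), the sterol transporter gene Gramd1b (1.03), the spectrin gene Sptb (0.88) and the mitochondrial kinase gene Adck1 (0.80) had positive log2 fold changes, with adjusted p up to 0.179, 0.222, 0.108 and 0.0891 over the omissions. Grxcr2 (-1.45), the peroxidasin gene Pxdn (-1.41), Sc5d (-1.22) and the macrophage gene Cd68 (-1.15) had negative ones, with adjusted p up to 0.234, 0.0812, 0.107 and 0.185. Gramd1b and Cd68 kept their calls only without WT 3, Thg1l without WT 2 or WT 3, Sptb and Sc5d without any WT library, Adck1 and Pxdn without any WT library or LXR DKO 1, and Grxcr2 only without WT 3 among the omissions in which it was tested. With no filter the calls of Thg1l (adjusted p = 0.0702), Gramd1b (0.0994), Grxcr2 (0.124), Sc5d (0.0648) and Cd68 (0.115) were also lost. Those of Thg1l (0.0618), Gramd1b (0.0848), Sc5d (0.0805) and Cd68 (0.0848) were lost without the oocyte-containing libraries, those of Cd68 (0.081) and Grxcr2 (0.0516) with voom, and that of Grxcr2 with a pseudocount of 0.1 (0.0599) and with the covariate (0.0539).

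All 15 macrophage genes tested had negative log2 fold changes in the transgenic libraries. Of these 1 fell (Cd68, from 44.2 ± 7.81 to 19.2 ± 2.6 RPKM), and 11 fell when adjusted over the list alone (median -1.15, camera adjusted p = 2.22e-17; adjusted p = 0.412 with an estimated correlation). All 11 oviduct epithelium genes had positive log2 fold changes, 0 past the threshold over all genes or over the list alone (median 1.13, camera adjusted p = 0.00034). With an estimated correlation the adjusted p = 0.586. Ovgp1 measured 453 ± 216 and 1601 ± 303 RPKM (1.93 ± 0.96, limma adjusted p = 0.66). The 27 cell cycle genes all had negative log2 fold changes, 0 past the threshold either way (median -0.19, camera adjusted p = 0.00034; adjusted p = 0.586 with an estimated correlation). That list's call was lost without LXR DKO 1, the LXR DKO library with the most oocyte RNA (camera adjusted p = 0.387). It was also lost without both oocyte-containing libraries (0.728), and in both settings the median was 1.3e-05.

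Among LXR targets 15 of 19 log2 fold changes were negative, 0 past the threshold over all genes or over the list alone, and the list was lower (median -0.12, camera adjusted p = 0.00845). With an estimated correlation the adjusted p = 0.412, and without LXR DKO 3 it was 0.144 with the preset correlation. The mixed test of fry did not pass (adjusted p = 0.238). The median ran from -0.20 (without transgenic 3) to -0.11 over the omissions. All 15 macrophage genes had negative log2 fold changes in the same libraries. Lpl measured 9.61 ± 1.21 and 6.12 ± 0.438 RPKM (-0.57 ± 0.15, limma adjusted p = 0.325), Mylip 1.55 ± 0.269 and 2.03 ± 0.470 RPKM (0.24 ± 0.19, adjusted p = 0.793), and Abca1 17.7 ± 2.96 and 16.3 ± 2.52 RPKM (-0.11 ± 0.23, adjusted p = 0.944). Sterol uptake and lipid droplet genes were lower as a list, with 0 of 20 past the threshold and 1 lower over the list alone (median -0.08, from -0.14 without LXR DKO 2 or transgenic 1 to -0.07 over the omissions, camera adjusted p = 0.00554; adjusted p = 0.412 with an estimated correlation). That gene was the scavenger receptor gene Cd36, at 12.1 ± 0.369 and 4.88 ± 1.06 RPKM (-1.17 ± 0.20, adjusted p = 0.0996). Cholesterol synthesis genes were lower as a list (median -0.06, camera adjusted p = 0.0265; adjusted p = 0.637 with an estimated correlation), with 1 of 24 past the threshold and the same gene, Sc5d, over the list alone. Luteinization (18 genes, 0 past the threshold, 1 lower over the list alone, median -0.17, adjusted p = 0.00034) and steroidogenesis (15 genes, 0 and 0, median -0.14, adjusted p = 0.0415) were also lower, each with adjusted p = 0.586 with an estimated correlation. Inflammatory genes (16 genes, 0 and 0, median -0.28, adjusted p = 0.00034) and lymphocyte genes (5 genes, 0 and 0, median -0.62, adjusted p = 0.0415) were lower too, each with adjusted p = 0.586 with an estimated correlation. Interferon response genes were higher (14 genes, 0 and 0, median 0.34, adjusted p = 0.0415; adjusted p = 0.692 with an estimated correlation). Omission of LXR DKO 1, LXR DKO 3 or transgenic 3 ended the calls of the cholesterol synthesis (adjusted p = 0.0663, 0.258 and 0.133), steroidogenesis (0.184, 0.144 and 0.212) and lymphocyte lists (0.116, 0.163 and 0.0921), the last also without transgenic 2 (0.0626). The inflammatory list was lost without LXR DKO 2 (median -0.033, adjusted p = 0.558), and the interferon list without WT 2, LXR DKO 3 or transgenic 2 (0.0517, 0.334 and 0.439). Over the omissions the medians ran from -0.14 to -0.022 for cholesterol synthesis (the latter without LXR DKO 3), -0.18 to -0.067 for steroidogenesis (without LXR DKO 1), -0.75 to -0.31 for lymphocyte genes (without LXR DKO 1), -0.46 to -0.033 for inflammatory genes (without LXR DKO 2) and 0.16 (without transgenic 2) to 0.57 for interferon genes. With the oviduct score as a covariate the luteinization and sterol uptake calls ended (adjusted p = 0.197 and 0.0535), as did those of the cell cycle (0.063), cholesterol synthesis (0.3), steroidogenesis (0.736), lymphocyte (0.258) and interferon lists (0.934), and by construction that of the oviduct list (0.706). The score was higher in every transgenic library (3.59 to 4.15) than in any LXR DKO library (2.40 to 3.21). Calls lost with it therefore cannot tell oviduct RNA from another difference between these genotypes. The medians with the covariate lay just above 0 for luteinization (0.013), sterol uptake (0.0076), steroidogenesis (0.013) and cholesterol synthesis (0.0021), and were -0.061 for cell cycle, -0.24 for lymphocyte and 0.12 for interferon genes. The steroidogenesis call also ended with quantile normalization (0.176), no filter (0.0528), the stricter filter (0.0521) and without the oocyte-containing libraries (0.176), the cholesterol synthesis call without those libraries (0.0651), and the interferon call with the stricter filter (0.0993), a pseudocount of 0.1 (0.0726) and voom (0.0508). No list passed the threshold with fry in 1 direction, where the lowest adjusted p was 0.174. The mixed test of fry passed for some lists, such as antioxidant (adjusted p = 0.003) and WNT response genes (0.00483).

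In all, 19 genes differed between transgenic and LXR DKO libraries in limma, 9 higher and 10 lower, 15 of them at least 2-fold apart. At an unadjusted p under 0.05 there were 1330, and the values of the groups did not overlap for 18.3% of genes tested against 10% by chance. The count was 9, 5 and 4 without LXR DKO 1, 2 and 3, 6, 7 and 7 without transgenic 1, 2 and 3, and 156 without WT 3. It was 31 with quantile normalization, 98 with only the 2 genotypes in the fit and 66 with the oviduct score as a covariate. The balance of directions also moved, with 104 higher and 52 lower without WT 3, and 16 higher and 50 lower with the covariate.

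Transgenic and WT libraries were compared to see which differences from WT the transgenic line retained. Among listed genes lower than in WT were Tnfaip6 (388 ± 63.2 to 135 ± 24 RPKM), the progesterone-forming enzyme gene Hsd3b1 (2201 ± 484 to 1076 ± 55.7 RPKM) and Lpl (17.5 ± 3.73 to 6.12 ± 0.438 RPKM; SD, n = 3). Adamts1 (13.2 ± 1.91 to 30.8 ± 3.23 RPKM) and Ptgfr (2.69 ± 0.733 to 6.06 ± 0.493 RPKM) were higher. Granulosa identity, immediate early and dissociation stress, macrophage and cell cycle genes were lower as lists in camera with a preset correlation, and glycolysis, oviduct and interferon genes higher. None of the 7 calls held with an estimated correlation (adjusted p = 0.811 each), and no single cell cycle or interferon gene passed.

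Of 19 LXR targets, 8 fell, 1 rose and 10 did not pass relative to WT, with 8 lower and 2 higher over the list alone (median -0.27, camera adjusted p = 0.196; 0.811 with an estimated correlation and 0.0498 with fry, which passes). The mixed test of fry passed too (adjusted p = 2.77e-07). Lpl fell by 1.36 ± 0.15 (limma adjusted p = 0.00169) and Apoe by 1.17 ± 0.19 (315 ± 95.2 to 136 ± 9.94 RPKM, adjusted p = 0.00844), both in every omission. In the same libraries the macrophage list had a median of -0.88. Mylip fell by 0.81 ± 0.19 (adjusted p = 0.0279), a call lost without WT 2 or any transgenic library (adjusted p up to 0.0925), with no filter (0.0731) or with only the 2 genotypes compared (0.0554). Lower too were Rnf145 (-0.58, adjusted p = 0.0154), the lipogenic transcription factor gene Srebf1 (-0.48, 0.0208), Scd2 (-0.76, 0.0288), the apolipoprotein gene Apoc1 (-1.01, 0.0376) and Abcg1 (-1.16, 0.0493), and the transglutaminase gene Tgm2 was higher (1.77, 0.0462). The call of Rnf145 was lost without transgenic 2 or 3 (adjusted p up to 0.058), and those of the other 5 without any transgenic library. Srebf1, Scd2 and Tgm2 lost theirs also without WT 1 or WT 2, Tgm2 without LXR DKO 3, Apoc1 without WT 1 or WT 3, and Abcg1 without any WT library or LXR DKO 1 (adjusted p up to 0.0715, 0.0976, 0.147, 0.114 and 0.142). All 6 were lost with the oviduct score as a covariate (adjusted p from 0.0569 for Apoc1 to 0.312 for Tgm2), and Scd2, Apoc1, Abcg1 and Tgm2 with no filter (0.0766, 0.0952, 0.12 and 0.114) and without the oocyte-containing libraries (0.0952, 0.118, 0.0957 and 0.0684). Single further losses were those of Scd2 with quantile normalization (0.069), Apoc1 with only the 2 genotypes compared (0.0643) or voom (0.052), Abcg1 without the trend (0.0514) and Tgm2 without the trend (0.0504) or with voom (0.0614). The remaining targets, none past the threshold, had log2 fold changes of 0.61 (Fasn), 0.36 (Smpdl3a), 0.34 (Scd1), 0.33 (Abca7), 0.31 (Lpcat3), 0.29 (Mertk), 0.26 (Abca1), 0.10 (Arl4c), -0.27 (Tmem97) and -0.54 (Pltp). Of 15 steroidogenesis genes 4 fell, 0 rose and 11 did not pass, with 5 lower and 1 higher over the list alone (camera adjusted p = 0.252). Hsd3b1 fell by 1.01 ± 0.18 (adjusted p = 0.0113) and its close copy Hsd3b6 by 0.95 ± 0.16 (26.9 ± 6.19 to 13.3 ± 1.34 RPKM, adjusted p = 0.0103), and reads shared between the copies make both uncertain. Of 18 luteinization genes 5 fell, 1 rose and 12 did not pass, with 5 lower and 3 higher over the list alone (camera adjusted p = 0.196). The prolactin receptor gene Prlr fell by 0.80 ± 0.14 (12.9 ± 2.05 to 6.95 ± 1.06 RPKM, adjusted p = 0.0118), and Ptgfr rose by 0.95 ± 0.16 (adjusted p = 0.00908). With the oviduct score as a covariate the calls of Hsd3b1 (-0.87, adjusted p = 0.0606), Hsd3b6 (-0.85, adjusted p = 0.0551) and Prlr (-0.61, adjusted p = 0.0722) were lost, and that of Hsd3b1 also with no filter (adjusted p = 0.0935). Of 22 cumulus expansion genes 5 fell, 1 rose and 16 did not pass, with 6 lower and 2 higher over the list alone (camera adjusted p = 0.449). Tnfaip6 fell by 1.52 ± 0.17 (adjusted p = 0.00134) and Adamts1 rose by 1.17 ± 0.17 (adjusted p = 0.00504).

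Of 21 granulosa identity genes 6 fell, 0 rose and 15 did not pass, with 12 lower over the list alone (median -0.51, camera adjusted p = 0.000935; adjusted p = 0.811 with an estimated correlation). The follistatin gene Fst fell by 0.96 ± 0.18 (127 ± 14.7 to 65.6 ± 10.6 RPKM, limma adjusted p = 0.0143; 0.0555 without transgenic 3 and 0.0866 with the oviduct score as a covariate). Of 21 immediate early and dissociation stress genes 8 fell, 0 rose and 13 did not pass, with 8 lower over the list alone (median -0.39, camera adjusted p = 0.000292; adjusted p = 0.811 with an estimated correlation). Jun fell by 0.81 ± 0.10 (adjusted p = 0.00205) and Jund by 1.24 ± 0.21 (43.9 ± 5.94 to 18 ± 0.957 RPKM, adjusted p = 0.011), the latter call lost with the oviduct score as a covariate (-0.93, adjusted p = 0.0663). Of 18 glycolysis genes 2 rose, 0 fell and 16 did not pass, with 12 higher over the list alone (median 0.32, camera adjusted p = 0.000271; adjusted p = 0.811 with an estimated correlation). Of 15 macrophage genes 5 fell, 0 rose and 10 did not pass, with 9 lower over the list alone (median -0.88, camera adjusted p = 0.000245; adjusted p = 0.811 with an estimated correlation). Cd68 fell by 1.23 ± 0.15 (46.5 ± 6.41 to 19.2 ± 2.6 RPKM, adjusted p = 0.00259) and the adaptor gene Tyrobp by 1.17 ± 0.20 (30.1 ± 7.16 to 12.6 ± 1.2 RPKM, adjusted p = 0.0112). Of 11 oviduct epithelium genes 2 rose and 9 did not pass, with 6 higher over the list alone (median 1.60, camera adjusted p = 0.000771; adjusted p = 0.811 with an estimated correlation), and the median was 2.57 without WT 3. The cadherin gene Cdh1 measured 8.96 ± 7.73 and 27.0 ± 3.16 RPKM (1.80 ± 0.49, adjusted p = 0.0466), a call held only without WT 3 (adjusted p up to 0.131 in the other omissions) and lost in most other settings, with an adjusted p of 0.0509 without the trend and 0.318 with the oviduct score as a covariate. Cell cycle genes were lower (27 genes, 0 past the threshold over all genes or the list alone, median -0.26, camera adjusted p = 0.00979) and interferon genes higher (14 genes, 0 and 0, median 0.92, adjusted p = 0.0201), each with adjusted p = 0.811 with an estimated correlation and each lost without WT 1 (0.259 for both, medians -0.10 and 0.49), the latter also without transgenic 2 (0.147). Both were also lost with the stricter filter (0.173 and 0.155) and without the oocyte-containing libraries (0.208 and 0.253). With fry in 1 direction only the glycolysis and the immediate early and dissociation stress calls among the 7 held. With the oviduct score as a covariate the calls of the granulosa identity (-0.33, adjusted p = 0.187), cell cycle (-0.026, 0.493) and interferon lists (0.40, 0.758) ended.

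The largest rises relative to WT included genes already high in LXR DKO, such as Ifi202b (4.33 ± 0.19, adjusted p = 1.29e-05), Fcrlb (3.29 ± 0.20, adjusted p = 6.11e-05), Hal (3.17 ± 0.15, adjusted p = 1.56e-05), Rbm45 (3.14 ± 0.12, adjusted p = 1.13e-05) and Acvrl1 (2.81 ± 0.14, adjusted p = 1.65e-05). Cav1 fell by 6.26 ± 0.53 (adjusted p = 0.00032) and Cav2 fell by 3.93 ± 0.19 (adjusted p = 1.65e-05), followed by Cntnap5a (-3.25), Nr1h2 (-2.70), Cercam (-2.32), Cd52 (-2.07) and Smarcd1 (-2.05). These 12 calls held in every omission in which the gene was tested. A2ml1 (4.11 ± 0.91), Ltf (3.13 ± 0.79), Lbp (2.75 ± 0.71) and Ctsk (-2.23 ± 0.53) lost theirs without WT 1, WT 2 or any transgenic library, Ltf also without LXR DKO 3 and Lbp also without LXR DKO 2 or LXR DKO 3, with adjusted p up to 0.0828, 0.114, 0.114 and 0.102. With the oviduct score as a covariate their log2 fold changes were 1.68, 1.02, 0.84 and -1.03 (adjusted p = 0.0666, 0.135, 0.144 and 0.194). All 4 calls were also lost with no filter (adjusted p = 0.0716, 0.0971, 0.102 and 0.084) and without the oocyte-containing libraries (0.0661, 0.0877, 0.0957 and 0.0985), and those of Ltf and Lbp with only the 2 genotypes compared (0.0616 and 0.0671). In WT 3, the WT library with the highest oviduct score, these 4 genes were closer to the transgenic libraries than in WT 1 or WT 2 (A2ml1 at 32.6, Ltf at 91.6, Lbp at 17.1 and Ctsk at 25.4 RPKM).

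In all, 1949 genes differed between transgenic and WT libraries in limma, 846 higher and 1103 lower, of which 357 were at least 2-fold apart. The values of the groups did not overlap for 35.7% of genes tested, against 10% by chance. The count was 908, 753 and 3442 without WT 1, 2 and 3, 734, 767 and 641 without transgenic 1, 2 and 3, and 1201 without both oocyte-containing libraries. It was 1096 with no filter and 1227 with the oviduct score as a covariate. Without WT 3 the balance turned, with 2018 genes higher and 1424 lower.

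The comparisons were set against each other to see how far the transgenic libraries differ from LXR DKO in the genes that LXR DKO changed. For the 1739 genes called between LXR DKO and WT, the transgenic mean lay a median of 12.5% of the way back to WT (quartiles -3.10% and 29.1%). For the 276 genes at least 2-fold apart it lay 7.74% of the way back (quartiles -2.82% and 23.8%). These genes were chosen on the same LXR DKO libraries, which by itself gives a value above 0. In 100 simulations in which transgenic and LXR DKO libraries have the same mean, the median averaged 7.70% (6.61% to 8.68%) for called genes. For those at least 2-fold apart it averaged 6.59% (4.37% to 10.2%). The value for all called genes lay above its simulated range and the other within it. These ranges are too narrow, because each gene was drawn independently and with the same spread in all genotypes. In the data genes varied together within genotypes, with mean residual correlations of 0.520 for macrophage and 0.866 for oviduct markers. Whether 12.5% exceeds the value with no transgene effect therefore cannot be told. The simulations called more genes (means of 3257 and 461), so their genes were less strictly selected than those of the data. Of the 1739 genes, 1175 (67.6%) were also called, in the same direction, between transgenic and WT. In the higher direction 366 genes were shared against 29.4 for independent lists, and in the lower direction 809 against 78.5. Genes called in opposite directions numbered 0 and 1, against 38.3 and 60.2. Across genes, which are not independent replicates, the correlation of both sets of log2 fold changes was 0.758 against a mean of 0.501 (0.444 to 0.555) in 100 simulations with no effect that share the WT libraries. The covariance was 0.131 against 0.0255. The groups are too small to split the WT libraries, so part of the excess may come from sharing them. The simulations also gave each gene the same spread in all genotypes. In the data the chi-square per degree of freedom between libraries was 46.0 to 139 within WT, 20.5 to 56.5 within LXR DKO and 16.8 to 20.9 within transgenic. A wider spread of the shared WT libraries by itself raises the correlation and the covariance, so the gap to the simulations decides nothing.

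Genes past the threshold in both steps with opposite signs, the reversed genes, numbered 12. Simulations with no genotype effect gave a mean of 0.01. They called means of only 0.09 genes in LXR DKO minus WT and 0.11 in transgenic minus LXR DKO. A count near 0 was therefore set in advance and is no measure for the 12. Reversed genes were not counted in simulations in which only WT stands apart. The groups are too small to split the LXR DKO libraries, so part of any excess over independent lists may come from sharing them. Of the 12 reversed genes, 7 were raised in LXR DKO and lowered by comparison in the transgenic libraries, against 0.347 for independent lists. The other 5 went the other way, against 0.641. None was called in the same direction in both steps, against 0.312 and 0.712 for independent lists. By the naming rule these were A2m (2.52 in LXR DKO minus WT, -2.03 in transgenic minus LXR DKO), Pxdn (1.74, -1.41), Zfp125 (2.22, -2.19), Grxcr2 (1.31, -1.45), Sc5d (0.73, -1.22), Adck1 (-0.59, 0.80) and Gpx3 (-0.55, 1.64). Gpx3 overshot, ending 1.09 ± 0.14 above WT (limma adjusted p = 0.00311), and the others did not differ from WT past the threshold, with Sc5d at an adjusted p of 0.0566. The call of Gpx3 between LXR DKO and WT (adjusted p = 0.0423) held in 1 of 9 omissions, that of LXR DKO 1 (adjusted p up to 0.149 in the others), and was lost without the trend (0.0501), with no filter (0.103), with only the 2 genotypes compared (0.102) and with voom (0.0511). The remaining reversed genes, Iah1 (0.71, -0.71), Gm9259 (-1.67, 1.32), Gm16381 (-1.99, 1.95), Gm2001 (-1.78, 1.79) and ENSMUSG00000116815 (1.07, -1.32), were chosen for naming after their values were seen. The number of reversed genes was 8 without WT 1, 36 without WT 3, 5, 1 and 0 without LXR DKO 1, 2 and 3, and 2, 2 and 3 without transgenic 1, 2 and 3. Of the 19 genes called between transgenic and LXR DKO, 9 lie on chromosome 12, which holds 4.06% of the genes tested, and 8 of these 9 are among the reversed genes. The log2 fold changes of both steps had a correlation across genes of -0.0912, against -0.498 in simulations, and a covariance of -0.0103 against -0.0253. Sharing the LXR DKO libraries by itself gives negative values, and the observed ones lay closer to 0. Unlike the data, the simulations held no difference between LXR DKO and WT and the same spread in all genotypes. The gap is therefore no measure of reversal.

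**Figure D4:**
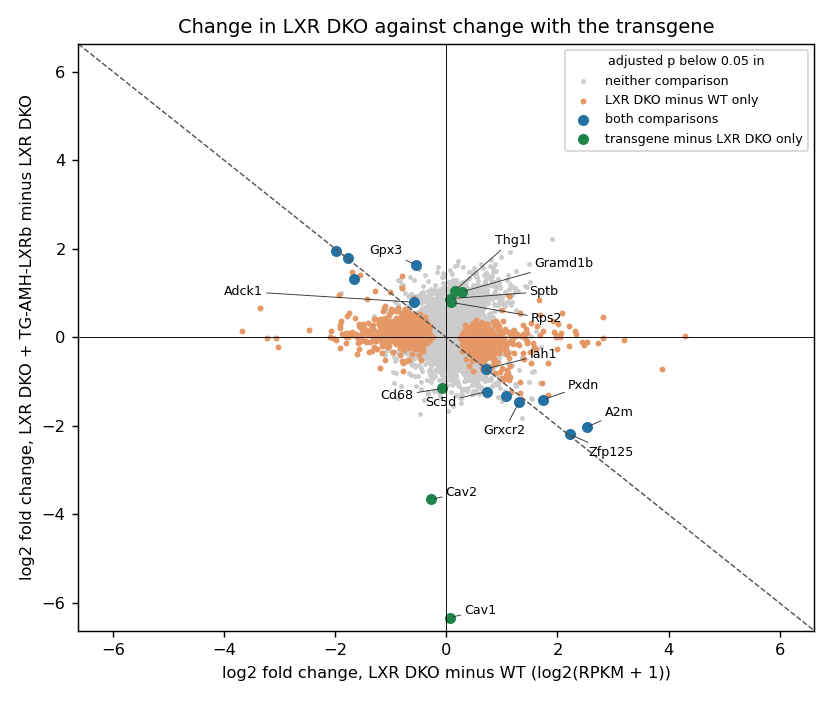
Log2 fold change of each tested gene in LXR DKO minus WT (horizontal axis) against transgenic minus LXR DKO (vertical axis), both on the log2(RPKM + 1) scale. The dashed line marks full reversal, and colours mark genes past an adjusted p of 0.05 in both comparisons (blue, 12 genes), in transgenic minus LXR DKO only (green, 7 genes), in LXR DKO minus WT only (orange) or in neither (grey).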

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

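Tests chosen only after seeing the data were voom on the reads worked back and the oviduct score as a covariate. Another left out the oocyte-containing libraries, WT 1 and LXR DKO 1. In limma, the 1739 genes called between LXR DKO and WT became 1032 with no filter, 902 with only the 2 genotypes compared, 1101 with the oocyte-containing libraries left out and 2721 with the covariate. The 19 called between transgenic and LXR DKO became 31 with quantile normalization, 98 with only the 2 genotypes compared and 66 with the covariate. The 1949 called between transgenic and WT became 1096 with no filter, 1201 with the oocyte-containing libraries left out and 1227 with the covariate. The 12 reversed genes became 22 with the covariate. No filter leaves more genes in the adjustment, and leaving out WT 1 and LXR DKO 1 leaves fewer libraries. The cause of the other changes was not tested. Of the 204 results of genes in the rule's set 159 were called, and none of these changed direction in any setting that tested them. Results not called were compared in direction only where a setting called them. Calls were lost for 66 of the 159 with no filter, 50 without the oocyte-containing libraries, 45 with the covariate and 39 with only the 2 genotypes compared. Fewer were lost with voom (14), quantile normalization (7), no trend (7), a pseudocount of 0.1 (3) and the stricter filter (0), which leaves some results untested.

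The 5 lists called between LXR DKO and WT, the 11 between transgenic and LXR DKO and the 7 between transgenic and WT became 0, 0 and 0 in camera with an estimated correlation, with 0, 3 and 1 lists at an unadjusted p under 0.05. With fry in 1 direction 4, 0 and 3 lists passed, 2, 0 and 2 of them among those called, with 7, 4 and 8 at an unadjusted p under 0.05. The lists that fry added were the p53 response and Sertoli lists between LXR DKO and WT (adjusted p = 0.03 each) and LXR targets between transgenic and WT (0.0498). The stricter filter left 3 lists between LXR DKO and WT. With the covariate 5 lists passed between transgenic and LXR DKO, 3 of them among the 11. The cause of these changes was not tested. With the covariate the camera direction of 3 called lists turned to lower: interferon response in transgenic minus LXR DKO (median still 0.12), and oviduct epithelium in transgenic minus LXR DKO (median -0.028) and in transgenic minus WT (median 0.034), the oviduct lists by construction. The medians of 4 others in transgenic minus LXR DKO turned to just above 0, from 0.0021 to 0.013, with the camera direction still lower.

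Leaving each library out in turn leaves 2 in its group. The genes called then ranged from 606 (without LXR DKO 3) to 2082 (without WT 3) for LXR DKO minus WT, from 4 (without LXR DKO 3) to 156 (without WT 3) for transgenic minus LXR DKO, and from 641 (without transgenic 3) to 3442 (without WT 3) for transgenic minus WT. The lists called ranged from 4 (without LXR DKO 2) to 9, from 6 (without LXR DKO 3) to 15 and from 6 (without WT 1) to 11, the highest always without WT 3. Reversed genes ranged from 0 (without LXR DKO 3) to 36 (without WT 3). Fewer libraries do not account for the rises without WT 3, whose cause was not tested. Of the called genes in the rule's set, 32 of 67, 5 of 14 and 35 of 78 kept their calls in every omission in which they were tested, and of the called lists 3 of 5, 4 of 11 and 5 of 7.

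Whether the replicate numbers pair the samples cannot be told, because the labels do not say and 3 libraries per genotype are too few to exclude it. Residual correlations of the 9 same-numbered pairs ran from -0.293 to 0.672, 3 of them above 0.1, and 3 of 9 libraries correlated best with their own number. The highest was that of WT 1 and LXR DKO 1, the 2 libraries with the most oocyte RNA. With the replicate block, 1178, 8 and 1513 genes were called in the 3 comparisons and 3 were reversed. Calls were lost for 26 results of genes in the rule's set and for the oxidative phosphorylation list in LXR DKO minus WT (adjusted p = 0.0519). Those lost in transgenic minus LXR DKO were Thg1l, Gramd1b, Sptb, Adck1, Grxcr2, Pxdn and Sc5d (adjusted p from 0.0681 to 0.105), and among the others were Lpcat3 (0.0641) and Gpx3 (0.0724) in LXR DKO minus WT. Small changes were mostly missed at this depth and number of libraries, neither of which was varied. In simulated data 18%, 18% and 14% of 1.5-fold changes were recovered in the 3 comparisons.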

Other observations

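Tests chosen only after the result was seen were those of pseudogenes, of macrophage and oviduct markers within genotypes, of blocks and of the number on 1 chromosome among the genes that differ between transgenic and LXR DKO, of smooth muscle markers, and of reversed genes with WT kept.

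Signalling and matrix genes also differed between LXR DKO and WT, and most of those named here differed in the same direction between transgenic and WT. Ctgf, a matrix-associated growth factor gene, rose from 4.10 ± 0.761 RPKM in WT to 18.5 ± 2.15 in LXR DKO and stood at 20.2 ± 1.98 in transgenic libraries (SD, n = 3; 1.94 ± 0.13 and 2.06 ± 0.13 against WT, limma adjusted p = 0.00011 and 7.2e-05). The WNT receptor gene Fzd1 fell from 48.8 ± 10.5 to 14.2 ± 1.80 and 14.6 ± 0.866 RPKM (-1.70 and -1.65, adjusted p = 0.000457 and 0.000544), and the chaperone gene Hyou1 rose from 13 ± 3.38 to 41.6 ± 3.97 and 49.8 ± 3.86 RPKM (1.63 and 1.88, adjusted p = 0.00117 and 0.000539). The matrix protease gene Mmp14 fell from 48.5 ± 7.24 to 24.6 ± 1.24 and 27.3 ± 2.74 RPKM (-0.94 and -0.80, adjusted p = 0.00286 and 0.00599). Mmp2 fell from 29.4 ± 4.11 to 14.1 ± 1.34 RPKM in LXR DKO (limma adjusted p = 0.00569) and measured 23 ± 4.40 RPKM in transgenic libraries, not past the threshold against WT (adjusted p = 0.156). All these calls held in every omission. As lists none passed in camera between LXR DKO and WT. Of 21 extracellular matrix genes 3 fell and 1 rose (4 and 3 adjusted over the list alone, camera adjusted p = 0.988), of 17 TGF-beta and BMP genes 3 fell and 2 rose (6 and 3, adjusted p = 0.511), and of 10 WNT genes 2 fell and 0 rose (2 and 0, adjusted p = 0.314). Of 19 unfolded protein response genes only Hyou1 passed, over all genes and over the list alone (adjusted p = 0.988, mean 0.03, median -0.08, direction lower). Between transgenic and LXR DKO these 4 lists had 0 members past the limma threshold over all genes (camera adjusted p = 0.0698, 0.128, 0.0865 and 0.128). Adjusted over the list alone, 2 matrix genes fell and 1 rose, 1 WNT gene fell and 1 rose, and 0 of the other lists passed.

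Lipid, stress and testis-related lists held few called members. In LXR DKO minus WT, fatty acid and triglyceride synthesis had 1 of 17 genes higher and 1 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.314), and fatty acid oxidation 1 of 18 higher (1 over the list alone, adjusted p = 0.409). The p53 response had 1 of 17 lower (2 lower and 1 higher over the list alone, adjusted p = 0.32), and Sertoli and testis determination 1 of 10 lower (1 over the list alone, adjusted p = 0.511). Of 18 antioxidant genes 1 rose and 2 fell (the same numbers over the list alone, adjusted p = 0.775, direction lower, mean 0.0095, median -0.06). Hmox1, the heme oxygenase gene, measured 21.4 ± 2.18, 48.2 ± 18.3 and 24.2 ± 3.84 RPKM in WT, LXR DKO and transgenic libraries (1.07 ± 0.23 in LXR DKO minus WT, limma adjusted p = 0.0236). Its call was lost without WT 1 or LXR DKO 2 (adjusted p = 0.0681 and 0.0609), with no filter (0.0673) and with only the 2 genotypes compared (0.0576). Of 5 theca and stroma genes 1 rose (2 over the list alone, camera adjusted p = 0.314), the matrix calcification inhibitor gene Mgp, from 13.5 ± 4.10 RPKM in WT to 35.3 ± 11.5 in LXR DKO (limma adjusted p = 0.0181). That call was lost without LXR DKO 2 or 3 (adjusted p = 0.0548 and 0.0552) and with no filter (0.0547). In transgenic libraries Mgp measured 51.1 ± 9.62 RPKM (adjusted p = 0.00504 against WT). Of the retinoid (8 tested), interferon (14), neutrophil (6), lymphocyte (5), ovarian surface (6), smooth muscle (7), erythroid (5) and oocyte (9) genes, 0 were called between LXR DKO and WT in limma, over all genes or over the list alone. Their camera adjusted p were 0.988, 0.314, 0.117, 0.988, 0.988, 0.988, 0.988 and 0.829. Likewise 0 of 27 cell cycle and 0 of 11 oviduct genes were called (adjusted p = 0.795 and 0.308). Mean and median differed in sign for the ovarian surface (0.12 and -0.036) and smooth muscle lists (-0.0096 and 0.08).

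Splits of the libraries into other groups were counted. A comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. The real splits gave 1739, 19 and 1949 genes, reached by 1, 1 and 1 of the 10 splits, and the highest other splits gave 1, 0 and 0. They gave 5, 11 and 7 lists, reached by 9, 3 and 6 of 10, and the highest others gave 17, 11 and 13. A structure of the samples other than genotype could give 17 lists, as could listed genes varying together more than the preset correlation of 0.01. These were not told apart. For reversed genes 2 of 100 groupings of the 9 libraries, the real one included, gave at least 12. The other gave 935 and keeps all 3 WT libraries together in the middle group, which points to the distance of WT from both knockout genotypes. That distance makes groupings that mix WT with the others no measure of chance here. Groupings that only rename whole genotypes were left out after a value was seen, which did not change the 2 of 100; with WT in the middle place such a grouping gives 1175. With WT kept, 1 of the 20 assignments of the other 6 libraries, the real one, gave 12 or more, and 20 are too few for a share under 0.05. The highest other, LXR DKO and transgenic exchanged, gave 8, and those that mix them gave 0.

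The genes at least 2-fold apart between LXR DKO and WT were weighed against DNA that differs between the lines, reads of gene copies, and RNA of oviduct cells. Argued against as the whole cause is DNA linked to the targeted loci, since 98.9% of the genes lay beyond 10 Mb of both. With the oviduct score as a covariate the median gene kept 98.4% of its log2 fold change (quartiles 94.2% and 102%). These genes therefore changed little with the score. The test cannot decide on oviduct RNA, because they were called without the covariate. The score ran from 1.47 to 3.84 within WT, so genes that follow it have a wide spread and are seldom called. Whether linked DNA adds genes cannot be told apart from no effect, with 3 of 254 tested genes near the loci against 1.68% elsewhere (odds ratio 0.701, 95% interval 0.143 to 2.09); the criterion written beforehand would have excluded it because the interval reaches below 1, and was set aside after the value was seen, since an interval up to 2.09 leaves room for an excess. Strain DNA in blocks may contribute, as 129 of the 271 genes beyond 10 Mb had another of them within 1 Mb (mean 81.2 and highest 107 in 1000 random draws), and reads of copies may too, as pseudogenes made up 28.8% against 23.5% (odds ratio 1.32, 1.002 to 1.73), although families of neighbouring copies also give blocks. An effect of LXR loss stays open and untested here, because any strain difference would go with genotype and the labels do not describe the background.

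Lower macrophage and higher oviduct markers in the transgenic libraries were weighed against varying amounts of such cells or their RNA in the samples; the labels name no sort that would remove them. Within genotypes the macrophage markers varied together between libraries with a mean residual correlation of 0.520, and the oviduct markers with 0.866, against a mean of 0.00331 and a highest value of 0.205 in 200 random lists of 15 genes. Abundant markers varied in this way within WT, with Ovgp1 at 1125 RPKM in WT 3 against 52.2 and 109 in WT 1 and 2, and Lyz2 at 878 RPKM against 343 and 365, while Lyz2 was at 329, 296 and 412 in transgenic 1 to 3. Both patterns are consistent with a varying share of co-collected cells, with all 15 macrophage and 11 of 12 oviduct markers past the filter, although Krt7 is also on the ovarian surface list and how many of the markers corona radiata cells themselves express was not tested. A change of these cells by the transgene, or of the same genes within corona radiata cells, stays open and untested.

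The genes that differ between transgenic and LXR DKO lay close together, with 14 of 19 having another within 10 Mb (mean 2.92 and highest 12 in 1000 random draws) and 9 on chromosome 12 (in 1000 draws of 19 tested genes the highest number on any chromosome had a mean of 3.27 and reached at most 8). A candidate explanation is DNA blocks that differ between the lines, in which case some reversed genes may follow a WT-like segment and not the transgene. For Cav1 and Cav2, a lost segment reaching the neighbouring genes is argued against, as 0 of the 9 other tested genes within 1 Mb were called lower than in LXR DKO by limma; Tes on one side kept 44.4 ± 5.56 against 59.4 ± 5.48 RPKM (-0.41 ± 0.11, adjusted p = 0.299, unadjusted p = 0.00366) while on the other side Met measured 1.65 ± 0.494 against 2.04 ± 0.233 (adjusted p = 0.794) and Capza2 kept 44.1 ± 0.954 against 55.2 ± 4.32 (-0.32 ± 0.09, adjusted p = 0.367, unadjusted p = 0.00819), although Tes was called lower than in WT (-0.71 ± 0.11, adjusted p = 0.0058). Less smooth muscle RNA is argued against too, since those markers had a median log2 fold change of 0.54 (0.15 to 1.12 over 7 markers). A loss limited to Cav1 and Cav2, a transgene insertion there, a partial effect on Tes or Capza2 and an effect of the transgene's product all stay open and untested.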
